A study of Mus musculus with 20 samples.

How the data were processed

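The series holds 20 small RNA libraries of mouse bone marrow cultures, 1 per combination of cell type (dendritic cells or macrophages), genotype (wild type or miR-155 knockout) and stimulus (none, LPS, oxLDL, eLDL or LDL). Per the labels' protocols, mice were 8 to 12 weeks old, dendritic cells were grown with GM-CSF and macrophages with M-CSF, and dendritic cells were stimulated overnight with 200 ng/ml LPS at day 8 to 9. The sample table takes day 8 to 9 for the dendritic cells with lipoproteins too, although the protocol does not name lipoproteins. The dose of the lipoproteins, and the dose and time for macrophages, are not given in the sources used here. Total RNA was extracted with Trizol and libraries were made with Illumina's TruSeq kit, per the labels' protocols.

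Each deposited file lists distinct sequences of 18 to 45 nt with the read count of each. CASAVA 1.8.2 is named per the submitters' processing notes, without its role. Adapter sequence was left in at most 0.03002% of the reads of a library, so the adapter had been removed before deposit, with a tool and length limits that are not given in the sources used here. The files hold no alignment and no miRNA names.

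Sequences of 18 to 26 nt were matched without mismatch to the 1178 miRNA hairpins of GENCODE release M21 (GRCm38). The arm was set by the terminal loop that RNAfold 2.7.2 predicts, and the start had to lie within 2 nt of the most abundant 5 prime end of the arm. Arms with identical or shared sequences formed 1 feature, and reads of sequences that fit several features were divided equally. This gave 1217 detected miRNAs. Tests took the 374 with at least 5 CPM in at least 2 libraries, which hold 99.96% or more of the miRNA counts of every library. Sequences outside annotated hairpins were not analysed here.

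Depth ran from 10.3 to 22.8 M reads and from 5.07 to 11.8 M miRNA reads per library. In the order unstimulated, LPS, oxLDL, eLDL and LDL, the miRNA reads in M (1e6) were 6.9, 8.8, 8.54, 5.07 and 6.97 in wild-type and 8.35, 10.6, 8.86, 6.42 and 5.91 in knockout dendritic cells, and 7.19, 7.97, 8.53, 6.44 and 11.8 in wild-type and 9.42, 7.85, 7.65, 7.2 and 6.91 in knockout macrophages. A count of 3, the upper 95% limit of a count of 0, is 0.255 to 0.592 CPM.

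Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3), with robust quasi-likelihood F tests and Benjamini-Hochberg adjustment at 0.05, in 1 fit of all 20 libraries. The main fit holds culture (cell type and genotype) and stimulus within cell type, with 8 residual degrees of freedom from the departures of the 2 genotypes from parallel responses. The knockout-against-wild-type LPS response used a fit with stimulus within genotype as well (4 degrees of freedom), and stimulus effects over both cell types a fit of culture and stimulus (12 degrees of freedom). With 1 library per condition, each is assumed to vary like the others. Standard errors are the log2 change divided by the square root of the F statistic. Ratios for single pairs use CPM of miRNA reads, with exact Poisson intervals at 95% for miR-155 and a pseudocount of 1 CPM for the pairs drawn in figures.

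The comparisons, tests, alternatives, lists and the rule for named miRNAs were fixed before the data were examined. The rule names miR-155, up to 12 miRNAs each way (5 for lipoproteins) with the largest called change, a mean of at least 50 counts and the same direction in every pair, the members of 16 lists, both arms of miR-455, miR-146a, miR-21a and miR-223 for LPS and genotype, and the 10 most abundant miRNAs of each cell type. Where calls were lost without a library, only some of the named miRNAs are described. Named outside the rule, and chosen after their values were seen, are miR-181a-1-3p with lipoproteins and miR-582-3p, miR-148a-3p and miR-378a-3p for genotype, all in macrophages. So are miR-1249-3p for the LPS difference between genotypes and the miRNAs given for effects over both cell types. Differences between cell types are also given for some miRNAs named only for the single cell types.

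The lists are inflammation-induced miRNAs, myeloid differentiation miRNAs, the let-7 family, the miR-99b/let-7e/miR-125a cluster, the miR-23/27/24 clusters, the miR-17~92 and paralogous clusters, the cluster of miR-183, miR-96 and miR-182, the miR-29 and miR-30 families, lipid handling miRNAs, and markers of erythroid, lymphoid, mast cell and granulocyte, stromal and mesenchymal, epithelial, endothelial and megakaryocyte, and liver and serum origin. They name 143 members, of which 119 were tested. Lists were tested with camera (limma 3.58.1) with a correlation of 0.01 between miRNAs and again with an estimated correlation, adjusted over the lists of a contrast. fry was run as a further test.

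The pipeline was tested on simulated data with the depths and fitted spread of the real libraries and a mean profile taken over all of them. Of simulated changes of log2 1, LPS in dendritic cells recovered 27 of 45 and genotype in macrophages 42 of 48; of changes of log2 2 these were 40 of 49 and 47 of 48. The difference of LPS responses between genotypes recovered 19 of 48 and 38 of 48. Each step made 1 to 3 false calls among unchanged miRNAs, and with no change simulated there were 0 to 1 calls. The simulated libraries were drawn independently, without the real cell type profiles and without variation between cultures or mice. These rates therefore do not cover errors from such variation.

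Alternatives were DESeq2 1.42.0 size factors, total miRNA reads and upper-quartile scaling, DESeq2's Wald test, limma-voom, no filter, a filter at 50 CPM, up to 3 untemplated 3 prime bases, only 20 to 24 nt, sequences of several features left out, an exact start, miR-155 left out before scaling, fits within 1 cell type, each library left out in turn, other pseudocounts and miR-155 per all reads in place of miRNA reads. After the data were seen, 2 were added: unread bases matched to any base, and both unstimulated macrophage libraries left out for the genotype effect in macrophages and its difference from dendritic cells. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. Messenger RNA targets were not analysed here, as the series holds none.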

Results

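Small RNAs of mouse bone marrow cultures were sequenced to follow miRNAs in dendritic cells and macrophages under LPS and lipoproteins, with and without miR-155. There are 20 libraries, 1 for each combination of 2 cell types, 2 genotypes and 5 stimulus states. Dendritic cells were grown with GM-CSF and macrophages with M-CSF, from wild-type C57BL/6 mice or from miR-155 knockout mice, and were left unstimulated or given LPS, oxLDL, eLDL or LDL. The labels do not spell out oxLDL and eLDL, and do not say whether the 5 libraries of a genotype and cell type came from separate mice or cultures. No condition has a replicate. A stimulus effect is therefore fitted over 2 matched pairs of libraries (wild type and knockout), a genotype effect over 5 matched pairs and the cell type difference over 10, and each is tested against the scatter between such pairs. Changes are log2 ratios with their standard error, tested with edgeR's quasi-likelihood test and called at an adjusted p (Benjamini-Hochberg) under 0.05.

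In the order unstimulated, LPS, oxLDL, eLDL and LDL, the dendritic cell libraries held 12.8, 13.9, 13.8, 10.6 and 13.2 M reads in the wild type and 14.7, 17.1, 15.2, 12 and 10.3 M in the knockout. The macrophage libraries held 13.5, 15, 17.6, 15.2 and 22.8 M in the wild type and 19.5, 16.2, 15.5, 15.9 and 15.3 M in the knockout. Between 42.35% and 63.39% of the reads of a library were assigned to miRNAs, which gave 1217 detected miRNAs, of which 374 were abundant enough to test. In dendritic cells miR-21a-5p was the most abundant miRNA with a mean of 26% of miRNA reads, followed by let-7f-5p with 8.15% and let-7a-5p with 5.51%. In macrophages miR-146b-5p led with 25.3%, ahead of miR-21a-5p with 14.1%, miR-181a-5p with 7.84% and let-7f-5p with 6.09%. The first principal component held 73.5% of the variance and separated the 2 cell types, and the second held 11.6%. On the first component the unstimulated wild-type macrophage library lay at 12.6, the unstimulated knockout one at 16.96 and the wild-type one with LPS at 16.99. The other macrophage libraries lay at 19.49 to 20.9. Both unstimulated macrophage libraries were thus nearer to the dendritic cells (−19.8 to −15.4) than those with a lipoprotein.

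The targeted miR-155 regulates inflammatory activation in myeloid cells. Its hairpin lies on chromosome 16 from 84714140 to 84714204 on the plus strand of GRCm38, in an exon of Mir155hg. In the wild-type dendritic cell libraries miR-155-5p stood at 129.3 CPM (counts scaled to 1e6 miRNA reads) unstimulated, 9589 under LPS, 447.3 under oxLDL, 341.3 under eLDL and 431.1 under LDL. These are ratios to the unstimulated library of 74.2 (95% counting interval 69.4 to 79.3), 3.46 (3.21 to 3.72), 2.64 (2.43 to 2.86) and 3.33 (3.09 to 3.60). Counting intervals, here and elsewhere, omit the scatter between cultures. In wild-type macrophages it stood at 5348 CPM unstimulated and 39830, 33140, 27240 and 26720 in that order. The ratios were 7.45 (7.37 to 7.53), 6.20 (6.13 to 6.26), 5.09 (5.04 to 5.15) and 5.0 (4.94 to 5.05). All share the unstimulated library, which lay nearest to the dendritic cells, and would shift with it.

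The knockout libraries held traces of miR-155-5p. The 5 knockout dendritic cell libraries had 2 to 7 reads each, 23 in all, or 0.0258% of the wild-type mean, to which the LPS library contributes most (0.17% without it). The 5 knockout macrophage libraries had 33 to 45 reads each, 183 in all, or 0.0179% of the wild-type mean. Over the 5 matched pairs miR-155-5p was lower in the knockout by 11.54 ± 0.78 on the log2 scale in dendritic cells (adjusted p = 1.2e-05) and by 12.40 ± 0.63 in macrophages (adjusted p = 3.2e-07). The passenger strand miR-155-3p had 0 reads in all 10 knockout libraries and also 0 in the wild-type dendritic cell library with oxLDL. With a floor of 3 counts, the knockout group was at least 169.9-fold lower in dendritic cells (461 reads in the wild-type group) and at least 2012-fold lower in macrophages (6482 reads). In dendritic cells 440 of those reads are in the library with LPS, and without the LPS libraries 21 remain and the bound is 7.52-fold (1445-fold in macrophages). In wild-type libraries miR-155-3p went from 1.305 CPM unstimulated to 49.98 CPM with LPS in dendritic cells, and from 32.01 to 221.2 CPM in macrophages.

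**Figure D1:**
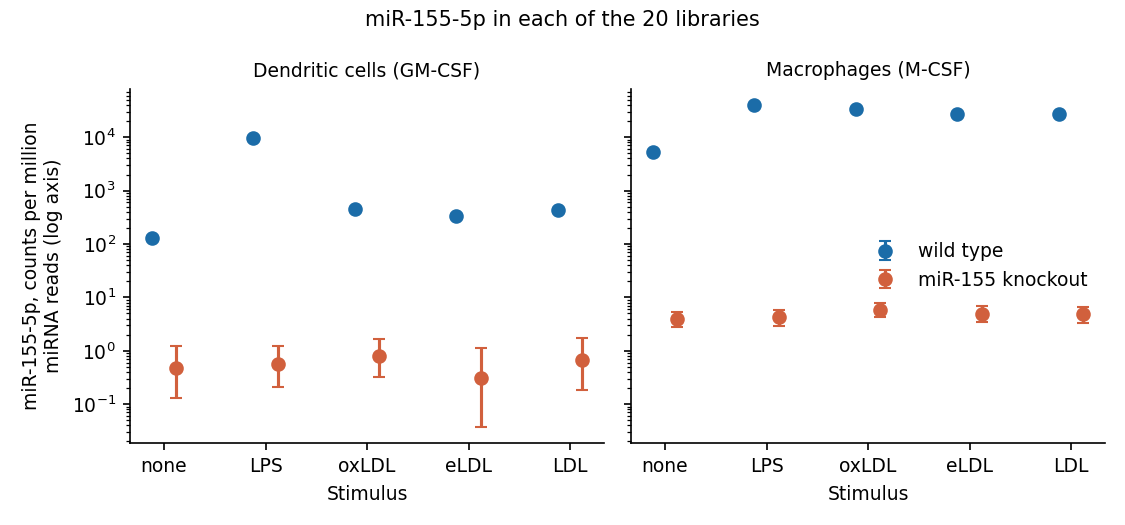
miR-155-5p in each of the 20 libraries, in CPM. Each point is 1 library with its 95% counting interval.

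LPS in dendritic cells asked which miRNAs follow maturation by a bacterial signal, in 2 pairs of libraries. Among the miRNAs named by the rule miR-147-3p, of an arm pair known to be induced by inflammatory signals, rose most, by 7.02 ± 0.35 (adjusted p = 1.6e-09). It went from 2.32 to 282.6 CPM in the wild type and from 3.47 to 266 CPM in the knockout. The other arm, miR-147-5p, rose by 4.44 ± 0.22. miR-92b-3p rose by 4.21 ± 0.58, miR-129-5p by 3.83 ± 0.58, miR-1945-3p by 3.23 ± 0.41, miR-21a-3p by 2.53 ± 0.29 and miR-210-3p, a miRNA induced by low oxygen, by 1.69 ± 0.28. miR-146b-5p, a brake on inflammatory signalling, rose by 0.83 ± 0.14, and its relative miR-146a-5p had 0.51 ± 0.18 (adjusted p = 0.0583). Of the miRNAs named by the rule whose call held without any 1 library, let-7c-3p fell most, by 2.82 ± 0.39 on the log2 scale, followed by miR-1843b-3p with −1.96 ± 0.41, miR-700-3p with −1.82 ± 0.29, miR-1249-3p with −1.74 ± 0.31, miR-181a-1-3p with −1.34 ± 0.16, miR-582-3p with −1.28 ± 0.18 and miR-93-3p with −1.21 ± 0.28. miR-223-3p, a regulator of granulocytes and of inflammatory signalling, fell by 0.84 ± 0.13 on the log2 scale (adjusted p = 0.00013). The hairpin of miR-147 lies on chromosome 2 from 122640803 to 122640881, in an exon of AA467197.

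In dendritic cells edgeR called 84 of 374 miRNAs for LPS, 46 higher and 38 lower, and 53 of the calls were larger than 2-fold. At unadjusted p under 0.05 there were 130, where 18.7 would be met with no change. Of the 24 miRNAs named by the rule fixed beforehand, 15 kept their call without any 1 library. Without the unstimulated wild-type dendritic cell library the count was 55, and without the wild-type library with LPS it was 53. miR-155-5p had a fitted value of 6.30 ± 1.04 (adjusted p = 0.0021), which is close to that of the wild-type pair alone (log2 ratio of CPM 6.20) and not to the mean with the knockout pair (0.08), as the fit follows the pair that holds nearly all the reads. It was not called without either of these 2 libraries (2.53 and 1.66). Scaled to total miRNA reads, the split was 26 higher and 125 lower, and all miRNAs shifted by −0.49 log2, and with upper-quartile scaling it was 33 and 45.

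The inflammation-induced list, 20 tested miRNAs reported to follow inflammatory signals, moved together in LPS dendritic cells: 14 rose, 1 fell and 5 were not called (15 and 1 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 1.7e-09, and adjusted p = 0.00299 with an estimated correlation). The list holds both arms of miR-155 and 4 arms of the miR-99b/let-7e/miR-125a cluster, and without these 6 it had 8 higher, 1 lower and 5 not called (camera adjusted p = 4.2e-05, and adjusted p = 0.0737 with an estimated correlation). Its members include let-7e-5p, which rose by 1.52 ± 0.20, and miR-125a-5p, which rose by 1.5 ± 0.22. The member that fell was miR-222-3p with −1.02 ± 0.24, whose call was lost without the unstimulated knockout dendritic cell library (−0.77) or the knockout one with LPS (−0.78). miR-21a-5p rose by 0.77 ± 0.18, a call lost without either of the same 2 libraries (0.62 and 0.64), with total reads (0.28) and with upper-quartile scaling (0.67). miR-455-3p had 4.86 ± 1.12 (adjusted p = 0.0083), lost without the unstimulated wild-type library (4.75), the wild-type one with LPS (4.04) or the unstimulated knockout one (5.02).

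miR-99b, let-7e and miR-125a are neighbours on the plus strand of chromosome 17, with hairpins from 17830188 to 17830257, from 17830352 to 17830444 and from 17830812 to 17830879, the first 2 in introns of Spaca6 and the third over an exon of Spaca6. The cluster rose in LPS dendritic cells: 5 of 6 arms rose, 0 fell and 1 was not called (5 and 0 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 0.00084, and adjusted p = 0.0864 with an estimated correlation). miR-125a-3p rose by 1.74 ± 0.21. miR-99b-5p rose by 0.69 ± 0.16, lost without the knockout dendritic cell library with LPS (0.47) and with total reads (0.21). The let-7 family, tumour suppressor miRNAs that repress Lin28 and Hmga2, had 3 members higher, 0 lower and 6 not called (4 and 0 adjusted over the list alone, camera adjusted p = 0.0205, and adjusted p = 0.681 with an estimated correlation).

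LPS in macrophages raised a partly different set. miR-129-5p rose by 2.80 ± 0.57 (adjusted p = 0.0020), miR-1948-3p by 2.61 ± 0.44, miR-8114-3p by 1.74 ± 0.32 and miR-147-3p by 1.41 ± 0.25, from 708.8 to 1898 CPM in the wild type and from 433.1 to 1158 CPM in the knockout. miR-146a-5p, which represses the adaptors Traf6 and Irak1, rose by 1.07 ± 0.19 (adjusted p = 0.00085), and miR-34a-5p, a target of p53, by 0.97 ± 0.19. Of the named miRNAs whose call held without any 1 library, miR-135a-3p fell most, by 2.50 ± 0.43 on the log2 scale, with miR-16-1-3p at −1.90 ± 0.22, miR-181a-1-3p at −1.85 ± 0.16, miR-342-5p at −1.64 ± 0.28, miR-700-3p at −1.45 ± 0.28, miR-27a-5p at −1.44 ± 0.18 and miR-223-3p at −1.08 ± 0.13. miR-378a-3p, encoded in the metabolic regulator Ppargc1b, fell by 1.21 ± 0.18 on the log2 scale. The values of the abundant miR-21a-5p and miR-146b-5p were −0.21 (adjusted p = 0.463) and −0.07 (adjusted p = 0.771).

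In macrophages edgeR called 69 of 374 miRNAs for LPS, 41 higher and 28 lower, 41 of them larger than 2-fold, with 112 at unadjusted p under 0.05. Of the 24 named by the rule, 13 kept their call without any 1 library. miR-132-3p, a miRNA induced by CREB, rose by 0.99 ± 0.21 but not without the unstimulated wild-type macrophage library (0.65). miR-92b-3p rose by 1.84 ± 0.52, a call lost without the unstimulated knockout macrophage library (1.05) or the knockout one with LPS (1.54).

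All 3 members of the cluster of miR-183, miR-96 and miR-182, known from sensory organs, rose with LPS in macrophages and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00068, and adjusted p = 0.112 with an estimated correlation), with miR-183-5p at 1.41 ± 0.18 and miR-182-5p at 1.31 ± 0.19. The third, miR-96-5p, had 1.70 ± 0.53 and lost its call without any 1 of the 4 unstimulated or LPS macrophage libraries (1.47 to 1.92). The miR-99b/let-7e/miR-125a cluster fell: 4 of 6 arms lower, 0 higher and 2 not called (0 and 4 adjusted over the list alone), with a median of −0.99 (camera adjusted p = 0.00068, and adjusted p = 0.112 with an estimated correlation), among them miR-99b-3p at −1.90 ± 0.26, let-7e-5p at −1.14 ± 0.20 and miR-99b-5p at −0.85 ± 0.16. Of the inflammation-induced list 6 rose, 3 fell and 11 were not called (6 and 3 adjusted over the list alone, camera adjusted p = 0.428). The 3 that fell are arms of that cluster. Without miR-155 and the 4 cluster arms 5 rose, 0 fell and 9 were not called (camera adjusted p = 0.0678, and adjusted p = 0.296 with an estimated correlation).

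**Figure D2:**
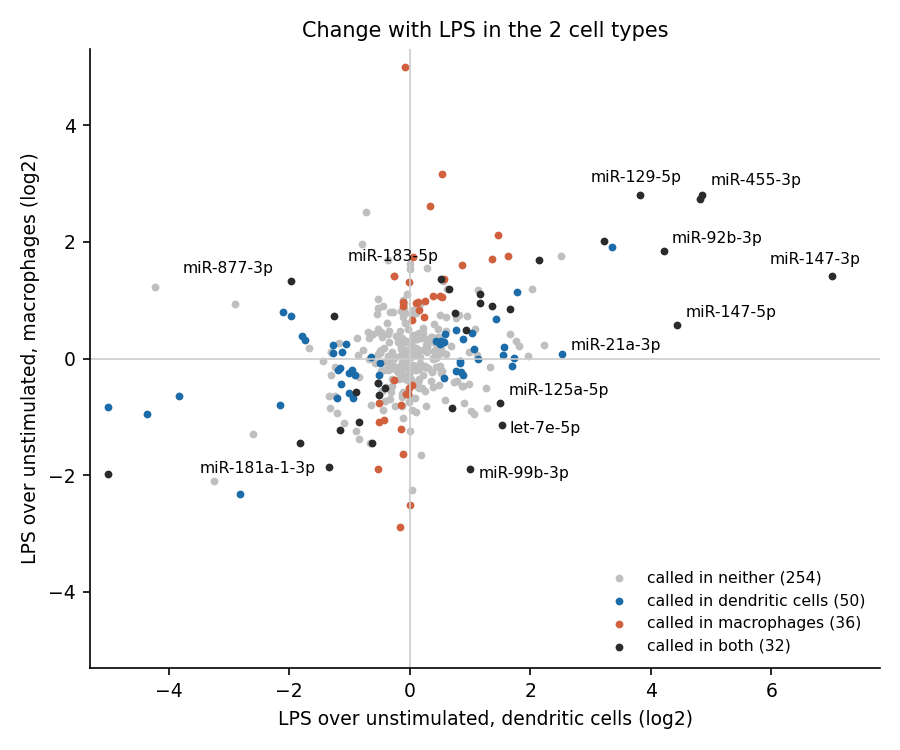
Effect of LPS in dendritic cells against that in macrophages for 372 miRNAs, miR-155 left out. Each point is 1 miRNA, and 3 lie at the edge of the plot.

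Whether LPS acts differently in the 2 cell types was tested as an interaction, which called 47 miRNAs, 21 with a more positive effect in macrophages and 26 with a more negative one (92 at unadjusted p under 0.05). The dose and time of LPS are not given for macrophages, and the cell types were sequenced apart. A difference in dose, time or run cannot be told apart here from one of cell type. The more negative ones included miR-147-3p (−5.61 ± 0.41, adjusted p = 3.2e-07), miR-147-5p (−3.86 ± 0.27), miR-99b-3p (−2.90 ± 0.35), let-7e-5p (−2.66 ± 0.29), miR-21a-3p (−2.46 ± 0.39) and miR-125a-5p (−2.27 ± 0.31). The differences of miR-146b-5p and miR-21a-5p, −0.90 ± 0.19 and −0.99 ± 0.26, were called, but not without the wild-type (−0.75 and −0.84) or the knockout (−0.70 and −0.77) LPS library of dendritic cells, nor with total reads (−0.40 and −0.47). miR-21a-5p was also uncalled with the upper quartile (−0.87) and without the unstimulated knockout dendritic cell (−0.83) or the unstimulated wild-type (−0.77), wild-type oxLDL (−0.96) or knockout LPS (−0.91) macrophage library. That of miR-378a-3p, −1.07 ± 0.24, was not called without the wild-type LPS library of dendritic cells (−0.85) or with total reads (−0.57), that of miR-16-1-3p, −1.38 ± 0.30, without the knockout one (−1.07), and that of miR-210-3p, −1.82 ± 0.39, without the unstimulated wild-type dendritic cell library (−2.0) or the knockout LPS one (−1.38), nor with total reads (−1.29) or the upper quartile (−1.67). Without any 1 library, 15 of the 24 named in this contrast kept their call. The more positive ones included miR-877-3p (3.30 ± 0.59), miR-1843b-3p (2.69 ± 0.57), miR-1249-3p (2.05 ± 0.43), miR-149-5p (1.98 ± 0.37), miR-183-5p (1.68 ± 0.26), miR-582-3p (1.37 ± 0.25) and miR-182-5p (1.32 ± 0.26). let-7e-5p, miR-125a-5p, miR-99b-3p and miR-99b-5p were called higher in dendritic cells and lower in macrophages. Of those, the miR-125a-5p effect in macrophages, −0.77 ± 0.22, was not called without the unstimulated wild-type (−0.56), the wild-type LPS (−0.80) or the knockout LPS macrophage library (−0.74), or without the knockout dendritic cell library with oxLDL (−0.68). miR-99b-5p and miR-99b-3p in dendritic cells were not called without the knockout library with LPS (0.47 and 0.53), nor miR-99b-3p without the unstimulated knockout one (0.90), nor either with total reads (0.21 and 0.52).

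Several LPS effects called in 1 or both cell types were not called as interactions: miR-146a-5p 0.56 ± 0.26 (adjusted p = 0.197), miR-132-3p 0.74 ± 0.30 (adjusted p = 0.143), miR-1945-3p −1.21 ± 0.59 (adjusted p = 0.22), miR-93-3p 0.53 ± 0.39 (adjusted p = 0.438), miR-222-3p 0.42 ± 0.34 (adjusted p = 0.468) and miR-96-5p 0.34 ± 0.87 (adjusted p = 0.855). So it was for miR-129-5p at −1.02 ± 0.78, miR-181a-1-3p at −0.51 ± 0.22 and miR-223-3p at −0.24 ± 0.18, each called in both. miR-155-5p had −4.29 ± 1.17 (adjusted p = 0.0446). The call was lost in most omissions of 1 library, and the value itself rests on the wild-type dendritic cell pair: without the one with LPS the value was 0.44, and without the unstimulated one −0.46. It was lost with upper-quartile scaling too (−4.06). The inflammation-induced list leaned to dendritic cells, with 0 of 20 more positive and 11 more negative in macrophages, 9 not called (1 and 11 adjusted over the list alone, camera adjusted p = 1.3e-07, and adjusted p = 0.00417 with an estimated correlation). Without miR-155 and the 4 cluster arms 0 of 14 were more positive, 5 more negative and 9 not called (camera adjusted p = 0.00968, and adjusted p = 0.246 with an estimated correlation). The miR-99b/let-7e/miR-125a cluster leaned the same way, with 0 and 5 of 6 and 1 not called (camera adjusted p = 4.2e-10, and adjusted p = 0.00417 with an estimated correlation). In the let-7 family 0 were more positive, 3 more negative and 6 not called (0 and 3 adjusted over the list alone, camera adjusted p = 0.00332, and adjusted p = 0.896 with an estimated correlation), and its median went from −0.43 to 0.07 when scaled to total reads. The cluster of miR-183, miR-96 and miR-182 had 2 more positive, 0 more negative and 1 not called (2 and 0 adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.246 with an estimated correlation).

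The count of the interaction was 30 without the unstimulated wild-type dendritic cell library, 26 without the wild-type one with LPS and 30 without the knockout macrophage library with LPS. Scaled to total reads it split into 79 and 12, with all miRNAs shifted by 0.497 log2, and with upper-quartile scaling into 23 and 16.

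Apart from miR-155, 16 miRNAs rose in both cell types, of 44 and 40 that rose in each, where 4.73 would be met if the calls were independent (Fisher's exact test, one-sided p = 8.5e-07). For those that fell it was 10 of 38 and 28, against 2.86 (Fisher's exact test, p = 0.00013). Across the 372 miRNAs, which are not independent replicates, the 2 effects had a correlation of 0.374. Averaged over both cell types (4 pairs of libraries), LPS raised 49 and lowered 36 miRNAs, and scaled to total reads 29 and 71, with all miRNAs shifted by −0.242 log2. A fit of only the 8 libraries of LPS and none called 15, 9 higher and 6 lower. Of the 24 named in this contrast 18 kept their call without any 1 library, among them miR-181a-1-3p at −1.63, miR-147-5p at 2.87 and miR-223-3p at −0.97.

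**Figure D3:**
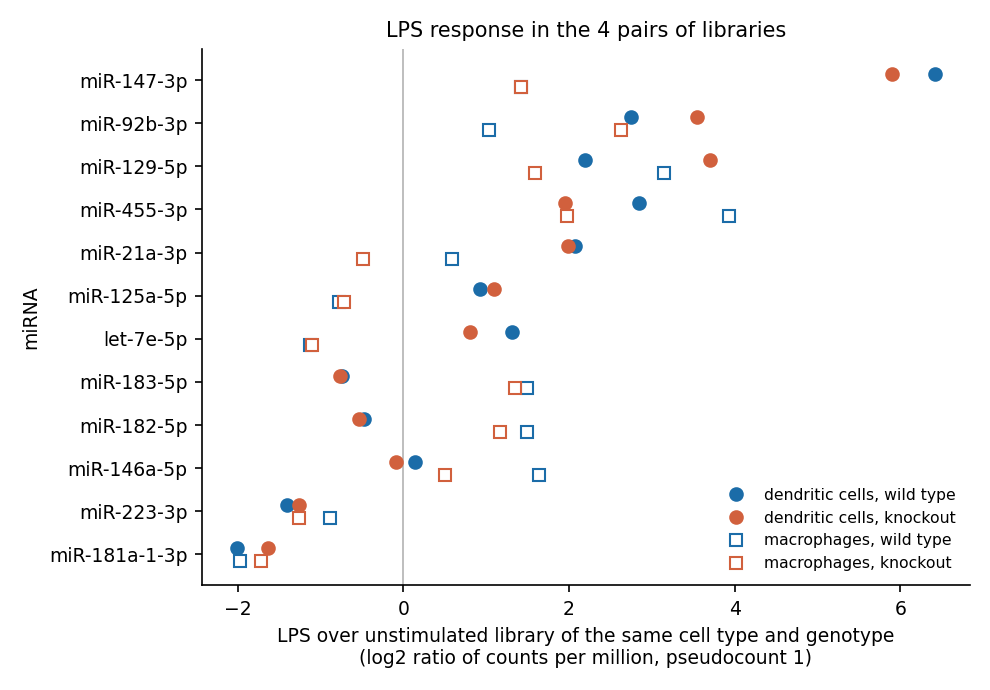
LPS over the unstimulated library of the same cell type and genotype for 12 miRNAs, as log2 ratios of CPM without the TMM scaling of the effects in the text. Each point is 1 pair of libraries.

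Whether the LPS response depends on miR-155 was tested over both cell types, as the knockout response minus the wild-type response (n = 2 pairs of each genotype). edgeR's quasi-likelihood test called 0 of 374 miRNAs. There were 17 at unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each. The smallest p belonged to miR-1249-3p (1.24 ± 0.30, adjusted p = 0.448) and to miR-155-5p itself (−3.66 ± 0.87, adjusted p = 0.448). miR-155-5p thus went uncalled, although its ratio of LPS to none was 7.45 in wild-type and 1.07 in knockout macrophages. Of simulated changes of log2 1 this contrast recovered 19 of 48. The 0 calls therefore do not show that the responses of the genotypes are alike. miR-455-3p had −2.12 ± 1.07 (adjusted p = 0.868) and miR-146a-5p −0.64 ± 0.24 (adjusted p = 0.864). Without the unstimulated knockout dendritic cell library there were 4 calls, and without any 1 of the 4 LPS libraries 1 each. Of the inflammation-induced list 0 rose, 0 fell and 20 were not called (0 and 1 adjusted over the list alone, camera adjusted p = 0.0151, and adjusted p = 0.357 with an estimated correlation, and 0.00669 and 0.312 without miR-155 and the 4 cluster arms). Without those arms the list test pointed to a lower LPS response in the knockout, with a median of −0.484.

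The lipoproteins were each compared with the unstimulated state in dendritic cells. oxLDL called 2 miRNAs, both higher: miR-181d-5p, of a family that tunes lymphocyte signalling, by 1.15 ± 0.22 and let-7e-5p by 1.04 ± 0.20 (adjusted p = 0.0179 for both). Neither held throughout. let-7e-5p was not called without the unstimulated wild-type dendritic cell library (0.85), the wild-type one with oxLDL (0.71) or the wild-type macrophage one with eLDL (1.03), nor with DESeq2 factors (1.04), total reads (0.85) or upper-quartile scaling (0.90). miR-181d-5p was not called without the wild-type oxLDL (1.32), unstimulated knockout (1.11) or knockout oxLDL (0.93) dendritic cell library, nor with total reads (0.97) or upper-quartile scaling (1.02). The count was 0, 1, 8 and 1 without the wild-type oxLDL, unstimulated knockout, knockout oxLDL dendritic cell and wild-type eLDL macrophage library. All miRNAs shifted by −0.188 log2 with total reads and −0.14 with upper-quartile scaling, and both gave 0 calls.

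For eLDL in dendritic cells edgeR called 0 miRNAs, with 28 at unadjusted p under 0.05, where DESeq2 called 2 and limma-voom 1. For LDL it called 0, with 27 at unadjusted p under 0.05, where DESeq2 called 8 and limma-voom 1. Leaving out 1 library gave 0 to 2 calls for either. With total reads all miRNAs shifted by −0.104 log2 for eLDL and −0.106 for LDL, and with upper-quartile scaling by −0.145 for eLDL.

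The miR-99b/let-7e/miR-125a cluster leaned upward as a group in dendritic cells with all 3 lipoproteins, with few single calls. The lipoproteins were compared with the same unstimulated libraries, so these are not separate observations. The arms come from neighbouring hairpins, for which the preset camera correlation of 0.01 may be too low. With oxLDL 1 of 6 arms rose, 0 fell and 5 were not called (4 and 0 adjusted over the list alone, median 0.62, camera adjusted p = 2.9e-06, and adjusted p = 0.0344 with an estimated correlation). With eLDL 0 rose or fell and 6 were not called (3 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 2.4e-06, and adjusted p = 0.0291 with an estimated correlation). With LDL it was again 0 and 6 (5 and 0 adjusted over the list alone, median 0.74, camera adjusted p = 1.0e-08, and adjusted p = 0.0092 with an estimated correlation). In the let-7 family with oxLDL 1 rose, 0 fell and 8 were not called (7 and 0 adjusted over the list alone, camera adjusted p = 1.2e-07, and adjusted p = 0.402 with an estimated correlation). Of the inflammation-induced list 20 were not called with eLDL (3 and 0 adjusted over the list alone, camera adjusted p = 0.00307, and adjusted p = 0.0567 with an estimated correlation) and 20 with LDL (4 and 0 adjusted over the list alone, camera adjusted p = 7.8e-05, and adjusted p = 0.0102 with an estimated correlation), but neither held without miR-155 and the 4 cluster arms (camera adjusted p = 0.236 and 0.133). With oxLDL 1 of that list rose, 0 fell and 19 were not called (4 and 1 adjusted over the list alone, camera adjusted p = 0.3), and its median of 0.12, mean of −0.28 and upward test differ in sign, as does its median with total reads (−0.07) or the upper quartile (−0.02).

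In macrophages all 3 lipoproteins lowered the same cluster and a group of other miRNAs. On the first principal component both unstimulated macrophage libraries lay nearer to the dendritic cells than those with a lipoprotein. The cluster was more abundant in dendritic cells, so its fall goes the way of that shift, whose cause was not tested. let-7e-5p fell by 1.40 ± 0.20 on the log2 scale with oxLDL (adjusted p = 0.00028), 1.44 ± 0.20 with eLDL and 1.27 ± 0.20 with LDL, from 1398 CPM to 525.5, 495.5 and 500.1 CPM in the wild type and from 283.5 to 154.7, 133.5 and 160 CPM in the knockout. miR-181a-1-3p was at −1.29 ± 0.15, −1.07 ± 0.15 and −0.98 ± 0.15 in the same order, called without any 1 library. miR-27a-5p was at −1.30 ± 0.17, −1.08 and −1.11 ± 0.17. miR-210-3p was at −1.53 ± 0.28, −1.24 ± 0.28 and −1.35 ± 0.28, while with LPS the 2 pairs went opposite ways, with a log2 ratio of CPM of 0.25 in the wild type and −0.61 in the knockout. miR-383-5p rose by 1.84 ± 0.51, 2.02 ± 0.52 and 1.96 ± 0.51, and miR-181c-5p by 1.03 ± 0.21 with eLDL and 0.98 ± 0.21 with LDL. miR-21a-5p, a miRNA known to repress Pdcd4, was at −0.99 ± 0.18 with oxLDL and −0.86 ± 0.18 with eLDL, and at −0.58 (adjusted p = 0.0598) with LDL.

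Many of these macrophage calls were lost when a single library was left out. Each stimulus effect is fitted over 2 pairs, so omitting a library of 1 pair also lowers the power of the test. A lost call is therefore no sign by itself that the value came from that library, and the values without it are given in brackets. let-7e-5p was not called for eLDL without the wild-type eLDL library (−1.33), nor for LDL without the wild-type LDL library (−1.06), nor was miR-27a-5p for eLDL without the former (−0.89). Without the wild-type library of the stimulus itself miR-210-3p was not called (−1.10, −0.97 and −1.15), nor for eLDL and LDL without the unstimulated wild-type library (−1.07 and −1.18), nor for LDL without the knockout LDL library (−1.46), nor for eLDL with total reads (−1.11). Without the unstimulated wild-type library miR-383-5p was not called (1.44, 1.61 and 1.56), nor miR-181c-5p (0.82 for eLDL and 0.77 for LDL). Without the wild-type and the knockout library of the stimulus miR-383-5p stood at 1.69 and 2.13 for oxLDL, 1.57 and 2.53 for eLDL and 1.79 and 2.26 for LDL, uncalled in each, as for oxLDL without the knockout LDL library (1.88) and for LDL without the knockout oxLDL library (2.0). miR-181c-5p was uncalled for eLDL without the wild-type (1.08) or knockout (0.99) eLDL library, and for LDL without the wild-type LDL library (0.88). miR-21a-5p was uncalled for oxLDL without the wild-type oxLDL library (−0.90), and for eLDL without the unstimulated wild-type (−0.65) or the wild-type eLDL (−0.48) library.

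edgeR called 44 miRNAs for oxLDL in macrophages (18 higher, 26 lower), 37 for eLDL (18 and 19) and 33 for LDL (15 and 18), with 78, 71 and 64 at unadjusted p under 0.05. Without the unstimulated wild-type macrophage library the counts were 24, 10 and 7. Without the wild-type library of the stimulus they were 4, 1 and 6, and without the knockout one 24, 18 and 15. Scaled to total reads the splits were 27 and 14, 27 and 13, and 17 and 13, and all miRNAs shifted by 0.247, 0.131 and 0.0978 log2. Differences between dendritic cells and macrophages in the lipoprotein effects were not tested. With upper-quartile scaling eLDL gave 15 and 19 (shift −0.103) and LDL 11 and 19 (shift −0.128).

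The miR-99b/let-7e/miR-125a cluster had 0 arms higher, 5 lower and 1 not called for each lipoprotein in macrophages. Here too the lipoproteins share the unstimulated libraries and the arms come from neighbouring hairpins. Adjusted over the list alone these were 0 and 5 for oxLDL, 0 and 6 for eLDL and 0 and 5 for LDL. The medians were −1.24, −1.19 and −0.94 and the camera adjusted p were 1.8e-09, 1.4e-08 and 5.6e-08, with adjusted p = 0.0114, 0.0154 and 0.0147 with an estimated correlation. Single calls were lost without the wild-type library of the stimulus. For eLDL these were let-7e-3p (−3.86), let-7e-5p (−1.33), miR-125a-5p (−0.97), miR-99b-3p (−1.17) and miR-99b-5p (−0.79). For LDL they were let-7e-5p (−1.06), miR-125a-3p (−0.48), miR-125a-5p (−0.85) and miR-99b-3p (−1.28). For oxLDL they were miR-125a-5p (−0.85), miR-99b-3p (−1.72) and miR-99b-5p (−0.86). Of the miR-23/27/24 clusters, 0 rose, 2 fell and 7 were not called with oxLDL (0 and 3 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.25 with an estimated correlation). Of the inflammation-induced list 3 rose, 8 fell and 9 were not called with oxLDL (5 and 8 adjusted over the list alone, camera adjusted p = 0.538), where the median of 0.305 and mean of 0.14 are positive, the test points down and the median without miR-155 is −0.04. For eLDL it was 3, 6 and 11 (6 and 7 adjusted over the list alone, camera adjusted p = 0.748) and for LDL 3, 5 and 12 (5 and 8 adjusted over the list alone, camera adjusted p = 0.633).

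The lipid handling list, which holds regulators of cholesterol export such as miR-33-5p, was not called in any contrast. Of its 11 tested members 0 rose, 1 fell and 10 were not called with oxLDL in macrophages (camera adjusted p = 0.721), 0, 0 and 11 with eLDL (camera adjusted p = 0.974) and 0, 1 and 10 with LDL (camera adjusted p = 0.971). With LPS 2 rose, 2 fell and 7 were not called in macrophages (3 and 2 adjusted over the list alone, camera adjusted p = 0.979), and 1, 2 and 8 in dendritic cells (camera adjusted p = 0.774).

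**Figure D4:**
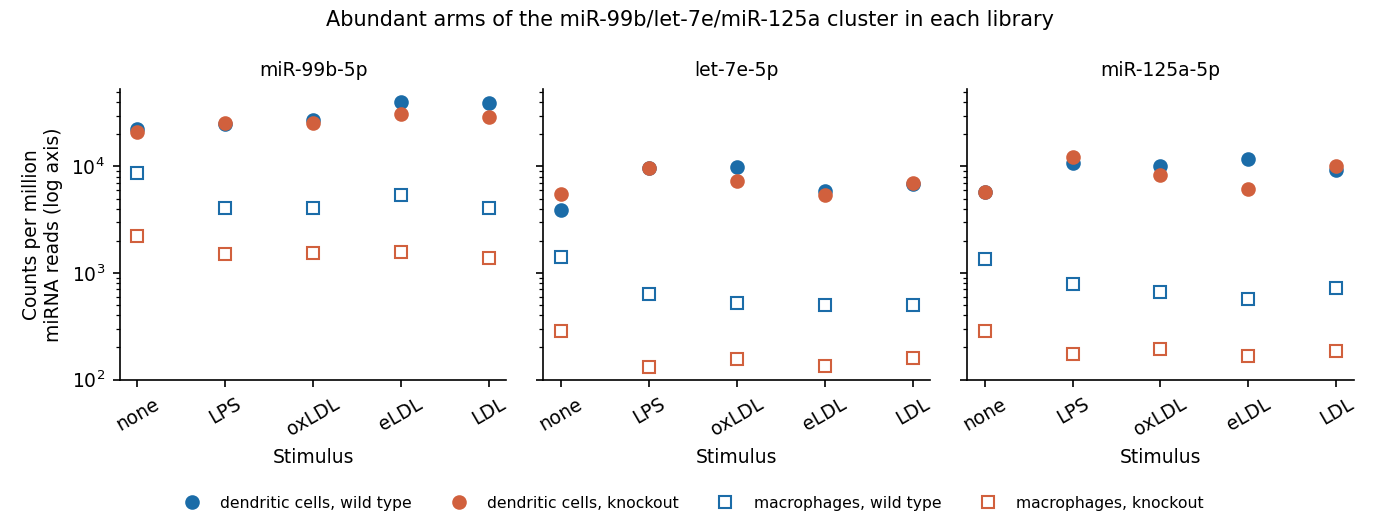
Abundant arms of the miR-99b/let-7e/miR-125a cluster in each library, in CPM on a log axis. Each point is 1 library.

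The stimuli share the same unstimulated libraries, which alone makes their effects run together. Across miRNAs, which are not independent replicates, LPS and oxLDL in macrophages had a correlation of 0.648 and a covariance of 0.437, where 40 simulations without any change gave 0.494 and 0.1. LPS and eLDL had 0.613 (simulated 0.485) and a covariance of 0.466 (0.102), and LPS and LDL 0.487 (simulated 0.505) and 0.307 (0.102). LPS and oxLDL both raised 14 miRNAs (1.83 if independent) and both lowered 16 (1.96). The shared libraries break that independence, so the expected counts are no measure of overlap without a shared response. The simulations called 0 miRNAs in both on average, but with no change simulated hardly any miRNA is called at all. They therefore give no measure of that overlap either. oxLDL and eLDL had 0.711 (simulated 0.501) and a covariance of 0.465 (0.103), with 15 raised and 17 lowered by both. In dendritic cells the correlations of LPS with oxLDL, eLDL and LDL, 0.239, 0.156 and 0.401, were below the simulated ones (0.483, 0.456 and 0.484), while the covariances, 0.207, 0.151 and 0.435, were above them (0.106, 0.105 and 0.11). Averaged over both cell types, oxLDL raised miR-127-3p by 1.65 ± 0.36 and lowered miR-181a-1-3p (−0.85 ± 0.17) and miR-140-3p (−0.42 ± 0.09, all adjusted p = 0.0342). Each of these 3 calls was lost without some 1 library, and the count ran from 0 to 8. eLDL gave 0 calls over both cell types (49 at unadjusted p under 0.05, DESeq2 7, limma-voom 0) and LDL 0 (43, DESeq2 2, limma-voom 5).

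The absence of miR-155 was compared in dendritic cells over 5 matched pairs. The labels do not say whether the 5 libraries of a genotype share a culture or mouse. If they do, a difference between cultures or mice cannot be told apart from one of genotype. The standard errors and p-values for genotype, here and in macrophages, cover only the scatter between the pairs. miR-582-3p rose by 2.70 ± 0.12 (adjusted p = 4.8e-11), from 10.7 to 32.0 CPM in the wild-type libraries to 61.8 to 232.5 CPM in the knockout ones. miR-139-5p rose by 0.97 ± 0.13, miR-146b-5p by 0.91 ± 0.09 (adjusted p = 2.9e-06), miR-342-3p by 0.62 ± 0.09 and miR-181a-5p by 0.43 ± 0.09. Next to miR-155 itself, miR-200b-3p, a guard of the epithelial state, fell by 1.19 ± 0.12 on the log2 scale (adjusted p = 6.1e-06), miR-34c-5p by 0.93 ± 0.20, miR-147-5p by 0.71 ± 0.15 and miR-148a-3p by 0.47 ± 0.09. miR-143-3p, a marker of smooth muscle and stromal cells, had −4.16 ± 0.91 (adjusted p = 0.0321), a call lost without any 1 of the 10 dendritic cell libraries (−3.98 to −4.33). The hairpin of miR-582 lies on chromosome 13 from 109324744 to 109324824, in an intron of Pde4d.

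edgeR called 25 miRNAs for the genotype in dendritic cells, 12 higher and 13 lower, with 76 at unadjusted p under 0.05. The count was 16 without the wild-type eLDL, the unstimulated knockout or the knockout eLDL dendritic cell library. The split was 18 and 13 with DESeq2 factors, 11 and 22 with total reads and 18 and 10 with upper-quartile scaling. It was 32 and 20 with DESeq2's Wald test, 21 and 17 in a fit of dendritic cells alone, 12 and 29 with the filter at 50 CPM and 11 and 38 with untemplated bases counted. In the inflammation-induced list 2 rose, 2 fell and 16 were not called (camera adjusted p = 0.859), with a median of 0.04, a mean of −0.95 that miR-155 carries, and a median of −0.02 with total reads. In the miR-99b/let-7e/miR-125a cluster 6 were not called (camera adjusted p = 0.747). Of the stromal and mesenchymal markers 0 rose, 1 fell and 4 were not called (0 and 2 adjusted over the list alone, camera adjusted p = 0.446).

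In macrophages the knockout differed more widely. The miR-99b/let-7e/miR-125a cluster was lower in the knockout: let-7e-5p by 2.14 ± 0.13 on the log2 scale (adjusted p = 3.2e-09), miR-125a-5p by 2.15 ± 0.14, miR-99b-3p by 2.56 ± 0.17 and miR-99b-5p by 1.79 ± 0.10. miR-210-3p fell by 3.06 ± 0.19 on the log2 scale, and miR-10a-5p, encoded in the HoxB cluster, by 1.39 ± 0.09, from 58720 to 82180 CPM in the wild type to 23170 to 37500 CPM in the knockout. miR-196b-5p, encoded in the HoxA cluster, was at −3.74 ± 0.68, miR-223-3p at −0.80 ± 0.08, miR-378a-3p at −0.80 ± 0.11 and miR-147-3p at −0.85 ± 0.16. miR-676-3p rose by 2.17 ± 0.23, miR-383-5p by 2.13 ± 0.32, miR-187-3p by 1.62 ± 0.39, miR-181d-5p by 1.45 ± 0.12 and miR-181c-5p by 1.22 ± 0.14. miR-34c-5p, a target of p53, rose by 1.24 ± 0.20, miR-30a-5p by 1.08 ± 0.12 and miR-146a-5p by 0.60 ± 0.12. miR-143-3p was lower in macrophages too (−4.06 ± 0.98), a call lost without the wild-type (−3.55) or the knockout (−3.60) oxLDL library. The hairpin of miR-210 lies on chromosome 7 from 141221384 to 141221493, outside other genes.

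edgeR called 91 miRNAs for the genotype in macrophages, 36 higher and 55 lower, with 127 at unadjusted p under 0.05. Of the 24 named, 22 kept their call without any 1 library. The split depends on scaling: 49 and 48 with DESeq2 factors, 65 and 41 with total reads (shift of all miRNAs 0.159 log2) and 116 and 33 with upper-quartile scaling (shift 0.343). Without both unstimulated macrophage libraries, of which the wild-type one stood apart, 30 rose and 49 fell.

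All 6 arms of the miR-99b/let-7e/miR-125a cluster fell in knockout macrophages and 0 rose (0 and 6 adjusted over the list alone, median −2.22, camera adjusted p = 3.7e-16, and adjusted p = 0.0029 with an estimated correlation), under every scaling. Of the inflammation-induced list 3 rose, 9 fell and 8 were not called (3 and 9 adjusted over the list alone, camera adjusted p = 1.1e-06, and adjusted p = 0.00632 with an estimated correlation), with a median of −0.23 that became 0.12 with upper-quartile scaling. Of the 9 that fell 6 are both arms of the deleted miR-155 and the 4 cluster arms, and without them 3 rose, 3 fell and 8 were not called (camera adjusted p = 0.997). Both tested endothelial and megakaryocyte markers fell, the 2 arms of miR-126a (0 and 2 adjusted over the list alone, camera adjusted p = 0.398), with miR-126a-3p at −1.56. Of the epithelial markers 0 rose, 3 fell and 3 were not called (1 and 3 adjusted over the list alone, camera adjusted p = 0.398), among them miR-200b-3p at −1.11. In LPS dendritic cells 3 epithelial markers rose, 0 fell and 3 were not called (4 and 0 adjusted over the list alone, camera adjusted p = 0.365). Each of these 3 calls was lost without some 1 library, such as miR-141-3p (1.03, then 0.30) and miR-200c-3p (0.76, then 0.44) without the wild-type dendritic cell library with LPS and miR-203-3p (1.78, then 1.60) without the knockout one. miR-141-3p and miR-200c-3p were also uncalled with total reads (0.53 and 0.27) and the upper quartile (0.93 and 0.66). Of the stromal and mesenchymal markers 0 rose, 1 fell and 4 were not called (camera adjusted p = 0.398), and of the miR-29 and miR-30 families, known to act on collagens and differentiation, 2 rose, 0 fell and 6 were not called (camera adjusted p = 0.398).

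**Figure D5:**
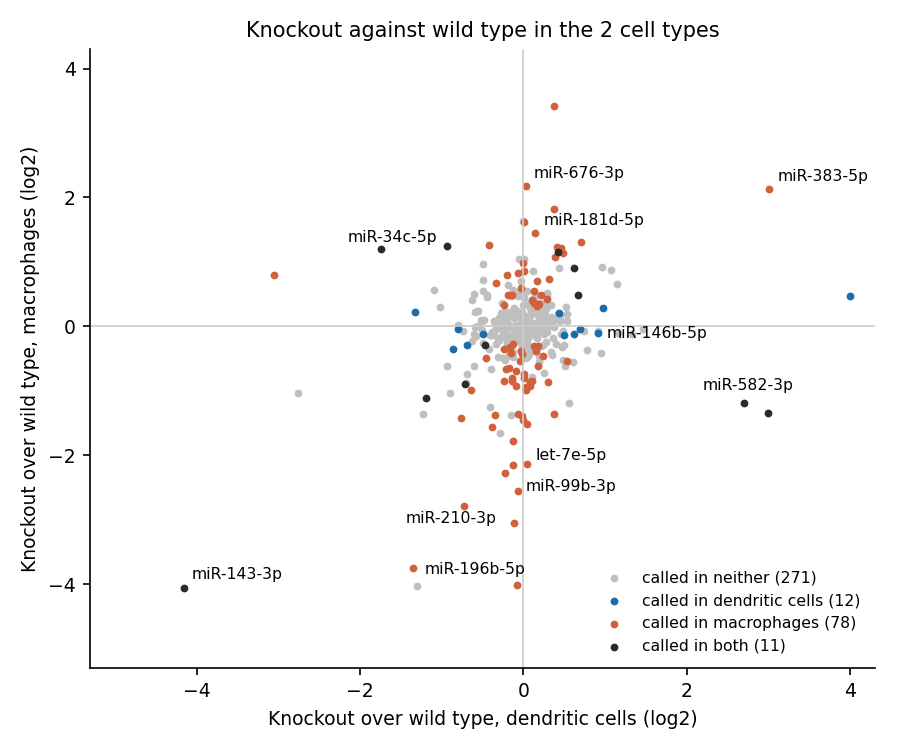
Knockout against wild type in dendritic cells and in macrophages for 372 miRNAs, miR-155 left out. Each point is 1 miRNA, and 1 lies at the edge of the plot.

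The difference between the 2 genotype effects, tested as an interaction, called 53 miRNAs, 18 more positive and 35 more negative in macrophages (89 at unadjusted p under 0.05). miR-582-3p, higher in knockout dendritic cells and lower in knockout macrophages (−1.19), led with −3.89 ± 0.16 (adjusted p = 1.9e-11), followed by miR-210-3p (−2.95 ± 0.25), miR-99b-3p (−2.49 ± 0.23), let-7e-5p (−2.18 ± 0.18), miR-125a-5p (−2.02 ± 0.20), miR-99b-5p (−1.66 ± 0.14), miR-10a-5p (−1.37 ± 0.12) and miR-146b-5p (−1.03 ± 0.12). More positive were miR-181c-3p (2.94 ± 0.53), miR-34c-5p (2.17 ± 0.28), miR-676-3p (2.14 ± 0.31) and miR-181d-5p (1.30 ± 0.18). miR-9-3p, with at most 3 reads in any dendritic cell library, had 3.85 ± 1.0, lost without the wild-type eLDL (3.25), wild-type LDL (3.19), knockout eLDL (3.25) or knockout LDL (3.25) dendritic cell library. For effects named in 1 cell type, the difference was −0.73 ± 0.12 for miR-342-3p, −0.81 ± 0.16 for miR-378a-3p, and uncalled for miR-147-3p (−0.70 ± 0.27, adjusted p = 0.114), miR-181a-5p (−0.22 ± 0.12, adjusted p = 0.294), miR-126a-3p (−1.18 ± 0.58, adjusted p = 0.227), miR-196b-5p (−2.39 ± 1.54, adjusted p = 0.375), miR-187-3p (1.62 ± 1.09, adjusted p = 0.407) and miR-383-5p (−0.88 ± 0.73, adjusted p = 0.491). miR-139-5p had −0.69 ± 0.19, lost without the unstimulated (−0.58) or the LDL (−0.62) knockout dendritic cell library, with total reads (−0.48) and with the upper quartile (−0.42), and miR-146a-5p 0.63 ± 0.16, lost without the wild-type macrophage library with LDL (0.59). Of the 24 named, 21 kept their call without any 1 library. Scaled to total reads the split was 43 and 25 (shift 0.215) and with upper-quartile scaling 51 and 20 (shift 0.275).

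All 6 arms of the miR-99b/let-7e/miR-125a cluster were among the more negative (median −2.12, camera adjusted p = 3.3e-12, and adjusted p = 0.00627 with an estimated correlation). Of the inflammation-induced list 1 was more positive, 9 more negative and 10 not called (1 and 10 adjusted over the list alone, camera adjusted p = 0.00042, and adjusted p = 0.0173 with an estimated correlation), and without miR-155 and the 4 cluster arms 1, 5 and 8 (camera adjusted p = 0.421). Of the mast cell and granulocyte markers 0 were more positive, 2 more negative and 3 not called (0 and 4 adjusted over the list alone, camera adjusted p = 0.0304, and adjusted p = 0.117 with an estimated correlation), with miR-223-3p at −0.66 ± 0.11, a call lost with upper-quartile scaling (−0.39). Apart from miR-155, 3 miRNAs rose with the knockout in both cell types (1.16 if independent, Fisher's exact test, one-sided p = 0.0996) and 4 fell (1.57, p = 0.0564): miR-143-3p, miR-147-5p, miR-148a-3p and miR-200b-3p. In macrophages miR-148a-3p had −0.28, a call lost without any 1 of the 6 macrophage libraries with a lipoprotein (−0.17 to −0.27), without 5 of the dendritic cell libraries (−0.22 to −0.28) and under every other scaling (−0.21, −0.12 and 0.06). Across 372 miRNAs, which are not independent replicates, the 2 genotype effects had a correlation of 0.243.

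The 2 cell types differed in most miRNAs. Macrophages had far more of miR-9-5p, known from neural cells (10.50 ± 0.19, adjusted p = 3.3e-15), miR-187-3p (8.29 ± 0.46) and miR-147-3p (6.59 ± 0.15), and of miR-146b-5p (4.50 ± 0.07, adjusted p = 1.6e-18). Dendritic cells had more of miR-99a-5p (−8.23 ± 0.19), of miR-125b-5p (−7.80 ± 0.12), a miRNA of blood stem and progenitor cells, and of miR-125a-5p (−4.43 ± 0.11), let-7e-5p (−4.33 ± 0.10) and miR-146a-5p (−3.27 ± 0.09). miR-223-3p differed by −0.50 ± 0.06. The cell types were also sequenced apart: 7.52% to 7.92% of reads of 20 nt or longer had an uncalled base at cycle 20 in the macrophage libraries and almost none did in the dendritic cell libraries, so cell type and run cannot be told apart.

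edgeR called 291 of 374 miRNAs between the cell types, 147 higher and 144 lower in macrophages, with 293 at unadjusted p under 0.05, and all 24 named kept their call without any 1 library. With upper-quartile scaling the split was 118 and 171 (shift −0.245). The miR-99b/let-7e/miR-125a cluster was lower in macrophages in all 6 arms (median −4.22, camera adjusted p = 0.00014, and adjusted p = 0.133 with an estimated correlation). The miR-23/27/24 clusters had 1 arm higher and 8 lower (camera adjusted p = 0.00514, and adjusted p = 0.16 with an estimated correlation), and the let-7 family 1 and 8 (camera adjusted p = 0.0194, and adjusted p = 0.658 with an estimated correlation). The cluster of miR-183, miR-96 and miR-182 was higher in all 3 (camera adjusted p = 0.0223, and adjusted p = 0.244 with an estimated correlation), as were the 3 liver and serum miRNAs (camera adjusted p = 0.0194, and adjusted p = 0.178 with an estimated correlation). Of the 5 lymphoid markers 4 were higher and 1 lower (camera adjusted p = 0.0173, and adjusted p = 0.133 with an estimated correlation). All these counts are the same adjusted over the list alone.

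Other lists were not called between the cell types. Of the myeloid differentiation list 5 were higher and 10 lower (camera adjusted p = 0.0528), of the erythroid markers 0 and 1 with 1 not called (camera adjusted p = 0.372), and of the inflammation-induced list 10 and 9 with 1 not called (camera adjusted p = 0.95), where the median of 2.20 and mean of 1.64 are positive and the test points down. With LPS the myeloid list had 2 higher, 2 lower and 11 not called in dendritic cells (3 and 2 adjusted over the list alone, camera adjusted p = 0.959) and 3, 3 and 9 in macrophages (camera adjusted p = 0.571). The miR-17~92 and paralogous clusters, known to drive proliferation, had 0 higher, 1 lower and 8 not called with LPS in both cell types (0 and 0 adjusted over the list alone in dendritic cells, 0 and 1 in macrophages, camera adjusted p = 0.774 and 0.428). The miR-29 and miR-30 families had 1, 1 and 6 in both (camera adjusted p = 0.997 and 0.979).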

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

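Both tests of the miR-155 traces, with the omission of single libraries from them, the test of the shared unstimulated libraries and the regroupings within matched pairs were chosen only after the result was seen. The others in this part were written beforehand, that of LPS activity in the preparations before its own values but after the single stimulus effects had been seen.

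The knockout libraries hold a few miR-155-5p reads. If reads carried over between libraries sequenced together, the traces would follow the wild-type level of the same cell type, and the share of that level in dendritic cells over that in macrophages was 1.48 (95% interval 0.914 to 2.29). That value rests on the wild-type dendritic cell library with LPS. Without it in the wild-type mean the ratio was 9.59 (5.93 to 14.8), and without the unstimulated wild-type macrophage library 1.77 (1.1 to 2.74), so the test leaves carry-over open. If the knockout cells still made a little miR-155 that answers LPS, the traces would rise with LPS as in the wild type (7.45 in macrophages). The ratio in knockout macrophages was 1.07 (0.649 to 1.76), so such expression alone does not account for the traces there. The interval covers only the error of counting, and a small responding part beside constant reads stays open. A residual expression that does not answer stimuli was not tested.

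The LPS and lipoprotein effects in macrophages run together across miRNAs. If the shared unstimulated libraries were the whole cause, the LPS response of 1 genotype would not follow a lipoprotein response of the other, but the mean of those 6 correlations was 0.292 (0.184 to 0.397), against 0.162 (0.076 to 0.245) in dendritic cells. If LPS activity in the lipoprotein preparations were the whole cause, at most 2 miRNAs were to go past their LPS response by a called difference, yet 8 did (miR-125a-3p, miR-181d-5p, miR-210-3p, miR-21a-3p, miR-21a-5p, miR-221-3p, miR-511-5p and miR-574-5p). These were chosen by a call of the lipoprotein effect, which favours large values there. The count also cannot exclude LPS activity at another dose or time, as neither is given for macrophages. A response that LPS and lipoproteins share in part remains possible. Neither explanation is excluded as a part of the cause.

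Knockout macrophages differ from wild type in more miRNAs than knockout dendritic cells do. The unstimulated wild-type macrophage library, which stood apart on the first principal component, is not the whole cause, since 79 miRNAs were called without it. A biological reading is that knockout macrophages lie further along the direction of the stimulus response. The stimulus effect from the eLDL, LDL and unstimulated libraries correlated with the genotype effect from the LPS and oxLDL libraries at 0.465 (0.368 to 0.559) across 372 miRNAs, which are not independent replicates, and at 0.148 in dendritic cells, which is consistent with that reading. A difference between the cultures or mice of the 2 genotypes could give the same and stays open, as the labels do not say how many there were.

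Regrouping the same libraries asks whether chance can be excluded. The effects were fitted over matched pairs of libraries, and the regroupings that keep these pairs number 8 for a stimulus over both cell types and 16 for the genotype and for its difference between the cell types, too few for a share under 0.05. There the real grouping against the highest other gave 85 against 5 calls for LPS, 3 against 2 for oxLDL, 0 against 0 for eLDL, 0 against 1 for LDL, 25 against 2 for the genotype in dendritic cells, 91 against 2 in macrophages and 53 against 1 for the difference. When only the 8 libraries of the stimulus and none were fitted, the 85 calls for LPS became 15 and the 3 for oxLDL became 0. Splits that ignore the pairs are more numerous but do not follow the design. Of 35 such splits 1, the real one, reached the count for LPS (highest other 14) and 1 for oxLDL (2), and all 35 did for eLDL and LDL (1 each). Of 100 splits 1 did for the genotype in dendritic cells (4), 1 in macrophages (38) and 1 for the difference (1). For the cell types 1 of 100 splits, the real one, reached 283 calls (highest other 165). So did 1 of 100 drawn from the 512 regroupings within pairs (highest other 231). These are counts of a simpler additive fit than the one that called 291. The regroupings treat each library as independent, while the labels do not say whether libraries of a genotype and cell type share a culture. They therefore cannot exclude chance differences between cultures or runs.

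LPS effects that a test found to differ between macrophages and dendritic cells numbered 47. The dose and time of LPS are not given for macrophages, so these differences cannot be assigned to cell type alone. Among the 24 that are named, 15 kept their call without any 1 library, and miR-26a-2-3p, miR-1948-3p, miR-8114-3p, miR-365-3p, miR-326-3p, miR-155-5p, miR-190b-5p, miR-210-3p and miR-338-5p did not. Those of named miRNAs that were more positive in macrophages were miR-877-3p 3.30, miR-26a-2-3p 2.90, miR-1843b-3p 2.69, miR-1948-3p 2.28, miR-1249-3p 2.05, miR-149-5p 1.98, miR-8114-3p 1.68, miR-183-5p 1.68, miR-365-3p 1.49, miR-582-3p 1.37, miR-182-5p 1.32 and miR-326-3p 1.30. More negative were miR-147-3p −5.61, miR-155-5p −4.29, miR-147-5p −3.86, miR-99b-3p −2.90, let-7e-5p −2.66, miR-21a-3p −2.46, miR-125a-5p −2.27, miR-190b-5p −1.91, miR-210-3p −1.82, miR-125a-3p −1.73, miR-338-5p −1.66 and miR-99b-5p −1.54.

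Genotype effects that differed between the cell types by the same kind of test numbered 53. The calls of 21 of the 24 named held in every omission of 1 library. Those of miR-9-3p, with at most 3 reads in any dendritic cell library (3.19 to 3.25 where lost), miR-92b-3p (1.35 to 1.58) and miR-1983-3p (0.66 to 0.76) did not. More positive in macrophages were miR-9-3p 3.85, miR-181c-3p 2.94, miR-34c-5p 2.17, miR-676-3p 2.14, miR-92b-3p 1.56, miR-181d-5p 1.30, miR-151-5p 1.0, miR-365-3p 0.99, miR-181c-5p 0.76, miR-1983-3p 0.75, miR-30a-3p 0.72 and miR-30a-5p 0.69. More negative were miR-582-3p −3.89, miR-210-3p −2.95, miR-99b-3p −2.49, let-7e-5p −2.18, miR-210-5p −2.06, miR-125a-3p −2.05, miR-125a-5p −2.02, miR-10a-3p −1.74, miR-99b-5p −1.66, miR-5114-5p −1.56, miR-10a-5p −1.37 and miR-21a-3p −1.16.

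Reads with an untemplated 3 prime U, which the comparisons do not use, had a larger share with LPS than unstimulated in dendritic cells, with a median change over miRNAs of 0.721 percentage points in the wild type and 0.517 in the knockout.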

How the results depend on the processing

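Of 229 values of named miRNAs, 2978 of 3133 recomputations under other settings kept direction and call. Of the others 119 lost the call, 7 gained one, 29 moved and 0 called values reversed. Values that moved were uncalled ones that changed sign, save 5 in dendritic cells and 5 in macrophages. Those were LPS differences between genotypes taken within a single cell type, which departed from the fitted value by at least its standard error. Leaving out a library kept 4203 of 4580, lost 344, gained 6, moved 26 and reversed 1: miR-155-5p, LPS effect, macrophages against dendritic cells, 0.44 without DC_WT_LPS replicate 1 (range without 1 library −5.83 to 0.44). For a stimulus effect in 1 cell type most of the omitted libraries are not part of its pairs, so the share kept overstates how firm such calls are. Of the named calls in macrophages, those kept in every omission were 2 of 10 for oxLDL, 0 of 10 for eLDL and 0 of 10 for LDL. For LPS there they were 13 of 24 and for genotype 22 of 24. Every alternative fixed before the data were seen was run. The filter at 50 CPM gives no value for miRNAs that it removes. The matching of unread bases and the omission of both unstimulated macrophage libraries were chosen after seeing the data, and with the latter 55 of 55 named values kept direction and call. Depth limits the rarest values most, such as miR-155-5p in the knockout. For the counts below the cause was not tested, except that fewer or more miRNAs are tested under other filters and fewer libraries in fits within 1 cell type or 8 libraries.

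Counts of called miRNAs by scaling were as follows. With DESeq2 size factors oxLDL, eLDL and LDL in dendritic cells gave 1, 1 and 1. With total miRNA reads LPS in dendritic cells gave 151, oxLDL there 0, the LPS difference between cell types 91, and oxLDL, eLDL and LDL over both cell types 5, 1 and 2. With the upper quartile oxLDL in dendritic cells gave 0, genotype in macrophages 149, and oxLDL, eLDL and LDL over both cell types 6, 1 and 2. With miR-155 left out before scaling eLDL in dendritic cells gave 1.

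By test, DESeq2's Wald test gave 6, 2 and 8 for oxLDL, eLDL and LDL in dendritic cells, 52 for genotype there, and 10, 7 and 2 for the 3 lipoproteins over both cell types. limma-voom gave 4, 1 and 1 for the lipoproteins in dendritic cells and 5 for LDL over both cell types. Fits within 1 cell type gave 2 for eLDL, 4 for LDL and 38 for genotype in dendritic cells. With only 8 libraries, LPS over both cell types gave 15 and oxLDL 0.

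By filter, no low count filter gave 12, 3 and 8 for the lipoproteins in dendritic cells, 4 for the LPS difference between genotypes and 18, 14 and 13 for the lipoproteins over both cell types. The filter at 50 CPM gave 0, 1 and 1 for the lipoproteins in dendritic cells, 41 for genotype there, 165 for the cell types and 4 for eLDL over both cell types.

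By assignment, counting untemplated bases gave 0 for oxLDL, 1 for eLDL and 49 for genotype in dendritic cells and 0 for oxLDL over both cell types. Only 20 to 24 nt gave 1 for eLDL in dendritic cells, and so did leaving out sequences of several features (1) and an exact start (1), which gave 1 and 1 for eLDL over both cell types.

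Without 1 library the counts ran from 53 to 93 for LPS in dendritic cells, 47 to 79 for LPS in macrophages, 0 to 8 and 4 to 49 for oxLDL in dendritic cells and macrophages, 0 to 2 and 1 to 40 for eLDL, 0 to 2 and 6 to 34 for LDL, 16 to 34 and 75 to 94 for genotype, 285 to 293 for cell type, 26 to 48 for the LPS and 44 to 59 for the genotype difference between cell types, 0 to 4 for the LPS difference between genotypes, and 61 to 89, 0 to 8, 0 to 6 and 0 to 2 for LPS, oxLDL, eLDL and LDL over both cell types.

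In single pairs 822 responses passed the size limit, and 393 with a pseudocount of 5 CPM. List tests gave 31 calls, 14 with an estimated correlation, and 27 without miR-155 and the cluster arms in the inflammation-induced list, an alternative chosen after seeing the data. Scaled to all reads in place of miRNA reads, miR-155-5p in wild-type dendritic cells had ratios of 87.26 with LPS, 3.977 with oxLDL and 2.348 with eLDL, and in macrophages 5.648 with oxLDL, 4.049 with eLDL and 4.848 with LDL.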

Other observations

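miR-511 is encoded in an intron of Mrc1, the gene of the macrophage mannose receptor, and was singled out after its values were seen. miR-511-5p was lower in macrophages than in dendritic cells by 3.16 ± 0.09 on the log2 scale (n = 10 pairs) and miR-511-3p by 2.12 ± 0.09. Both arms were lower in knockout macrophages, with −0.98 ± 0.13 (adjusted p = 2.0e-05) and −0.94 ± 0.12 (adjusted p = 1.5e-05), and stood at 0.03 and 0.04 in dendritic cells (adjusted p = 0.932 for both). The genotype effects differed between the cell types by −1.02 ± 0.17 and −0.98 ± 0.17 (adjusted p = 0.00052 for both). With LPS miR-511-5p rose by 1.07 ± 0.19 in dendritic cells, while miR-511-3p had −0.15 (adjusted p = 0.649). All these calls held without any 1 library. In macrophages miR-511-3p fell with LPS (−0.80), oxLDL (−1.12), eLDL (−0.99) and LDL (−0.95). miR-511-5p fell there with oxLDL (−0.82), eLDL (−0.82) and LDL (−0.70). Each of these macrophage stimulus calls was lost without some 1 library. miR-503-5p, a member of the myeloid list, rose with LPS in dendritic cells by 1.37, a call kept in every omission.

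The mean of the 3 lipoprotein effects was fitted after the single effects had been seen. In macrophages 18 miRNAs rose and 28 fell, and in dendritic cells 0 rose and 0 fell. The mean lipoprotein effect differed from the LPS effect in 49 miRNAs in macrophages and in 90 in dendritic cells. Among the latter were miR-147-3p, whose mean lipoprotein effect was 0.49 ± 0.33 (adjusted p = 0.615) against 7.02 with LPS, and miR-129-5p, with 0.81 ± 0.48 (adjusted p = 0.568) against 3.83.

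Hypotheses on arms and on U tails were looked at in the same data. The test of the arms was written beforehand and the test of the U tails was chosen only after the result was seen. One hypothesis was that the less abundant arm of a hairpin follows LPS with a larger change than the abundant arm. Of 58 cases with a called abundant arm, the other arm had the larger change in the same direction in 18, 11 of 29 in dendritic cells and 7 of 29 in macrophages. The cases were chosen by a call of the abundant arm, which favours a large change there, so this count cannot decide for or against the hypothesis. Across 106 hairpins, which are not independent replicates, the changes of the 2 arms had a correlation of 0.594 in dendritic cells and 0.419 in macrophages.

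The other hypothesis was that LPS raises the share of reads with an untemplated 3 prime U in dendritic cells. It was higher with LPS in both genotypes for 82 of 132 miRNAs with at least 300 reads in each library, against 61 with oxLDL, 55 with eLDL and 57 with LDL, and 48 with LPS in macrophages. The hypothesis came from the rise of that share in the same libraries, so these counts describe it and are no separate test of it.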
